A study of Mus musculus with 3 samples.

How the data were processed

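Nuclear RNA from abdominal aortae was measured by droplet-based single-nucleus RNA sequencing. The animals were ApoE-/- mice on a C57Bl/6 background, kept on a high-fat diet and exposed to room air or cigarette smoke for 20 weeks. ApoE-/- mice lack a working apolipoprotein E, clear lipoprotein remnants poorly and develop atherosclerosis. There were 3 libraries, 1 for each of 3 groups: room air (the room air library), smoke without an abdominal aortic aneurysm (the smoke library) and smoke with an aneurysm (the aneurysm library). How many animals each library holds is not given in the sources used here. Per the labels' protocols, frozen aortae were lysed and homogenised, and nuclei were then purified on a magnetic column with anti-nucleus beads, a sort that can itself set the share of each cell type.

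The deposited values are raw UMI counts per gene and barcode, with no normalisation, for 33696 gene features that the authors paired with Ensembl mouse identifiers and symbols. The matrices came from cellranger 8.0.1 per the file headers, whereas the submitters' processing notes name Cell Ranger 2.2.0, STAR and the mm10 build. This conflict was not resolved, so no coordinates are given. Of the features, 31961 had their identifier in the reference annotation. The lowest total of any deposited barcode was 500 UMIs in each library, so the authors' cell calling had set a minimum. Strand handling and intron counting are not given in the sources used here, so UMIs of overlapping or antisense genes cannot be told apart.

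All settings in this paragraph were fixed before the data were examined. Barcodes were kept with at least 500 UMIs, at least 300 genes and under 5% of UMIs on mitochondrial (mt-) genes. Scrublet, as built into scanpy, was run per library with an expected doublet rate of 0.8% per 1000 barcodes, which gave 10.5%, 11.9% and 5.88%. Its automatic threshold marked 1 of 13189 barcodes of the room air library and 6 of 7348 of the aneurysm library, and no threshold was found for the smoke library. The caller therefore did not work in these libraries, and doublets remain in the data. Counts were scaled to 10000 per nucleus and log-transformed, 2000 variable genes chosen within libraries and 30 principal components were taken, and a graph of 20 nearest neighbours was clustered by the Leiden method at resolution 1. No batch integration was made, since library and group are the same thing. This gave 31 clusters of 30724 nuclei out of 35396 barcodes.

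Clusters were named from fixed marker sets of 24 cell classes. A name needed a mean marker score of 0.5 (log2 over the median cluster), at least 3 markers detected in 5% of nuclei, a margin of 0.25 over the runner-up, and among the top 10 genes no more markers of other classes than of its own. A shallow cluster with none of its markers there stayed unnamed. The score and margin were set after seeing the data, so the share of every unnamed cluster is given. Named classes are written as "-like", since names rest on marker genes alone.

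UMIs were summed over the nuclei of a class in each library and divided by the class total, scaled to CPM. A class needed 50 nuclei in both libraries compared. Shares carry exact Clopper-Pearson intervals, CPM exact Poisson intervals, and CPM ratios exact conditional binomial intervals, all at 95% and all covering counting error only. With 1 library per group there is no test and no replicate check of any difference, and no p-value is given. A gene without a UMI in 1 library was compared with a floor of 3 counts over the class, written as "at least"; the exact 95% bound, which also covers the error of the other count and so lies lower, is given after it as "bound". For 19 gene lists fixed in advance, the median log2 CPM ratio was taken over members with at least 20 UMIs in both libraries together, with members at 0 set at that floor, or left out where the floor passed the CPM of the other library. Its counting interval comes from 1000 Poisson redraws. Its percentile among 10000 random lists of equal size, matched on mean expression in 20 bins, describes these libraries. Members at least 1.5 times higher or lower were counted. Of the list symbols, 1 (Ctgf) was missing from the features under that name; Ccn2, its current symbol, was on the same list.

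Named genes were taken by a rule that ranked genes by the bound of the CPM ratio nearest 1. In the comparisons of smoke with room air and of aneurysm with smoke, it took up to 7 genes per direction in macrophage-like, 4 in smooth muscle-like, 4 in fibroblast-like and 2 in endothelial-like nuclei. In the comparison of aneurysm with room air it took 4 per direction in macrophage-like nuclei. A gene needed 30 UMIs in the library where it was higher, a bound at least 1.5 times from 1, and there a CPM no lower than in all other nuclei, as a guard against free RNA. Predicted Gm and Rik genes, mitochondrial, ribosomal protein, haemoglobin and sex-linked check genes were left out. Members of fixed lists were named as those with the most UMIs or the largest ratios. Some genes taken by the rule or leading a cluster are not reported here.

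The ratio step was tested on simulated counts with 100 genes changed at each fold. At a 2-fold change it recovered 81% for smoke against room air (17054 genes), 75% for aneurysm against smoke (16884 genes) and 74% for aneurysm against room air (15291 genes). At a 4-fold change the shares were 100%, 100% and 98%. Intervals covered the true ratio for 95.5%, 96.9% and 96.7% of genes, and 1, 3 and 4 unchanged genes passed the rule. Counts were Poisson draws based on the macrophage-like sums, the model that the intervals assume, so coverage near 95% was set by design. UMIs clumped in single nuclei and the guard against free RNA were not simulated. Recovery, coverage and false calls can thus be worse in the real data.

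Alternatives fixed in advance were a minimum of 1000 UMIs, no filter on barcodes, Scrublet calls kept, Leiden resolutions 0.5 and 2, 15 principal components, libraries clustered one by one and nuclei thinned to 1000 UMIs. Others were median-of-ratios and TMM scaling, other count minimums, removal of genes below the other nuclei, and wall and immune classes as the denominator. The alternatives chosen after seeing the data left out the highest Scrublet scores, assigned unnamed clusters to their best-scoring class, used cluster 0 or cluster 17 alone, asked for 5 expected UMIs per list member, or dropped the mitochondrial limit. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2 and igraph 0.11.9.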

Results

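The room air library held 13189 barcodes and 73891039 UMIs, the smoke library 14859 barcodes and 117247048 UMIs, and the aneurysm library 7348 barcodes and 15634797 UMIs. After filtering, 11021, 14001 and 5702 nuclei remained, with medians of 4058, 6225 and 1443 UMIs and of 1827, 2357 and 902 genes per nucleus. The aneurysm library was thus the shallowest, and its values have the widest counting intervals. Each group is 1 library, so every difference below is a difference between libraries.

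Apoe (ENSMUSG00000002985), the gene disrupted in these mice, was at 3.63 CPM (3.19 to 4.11; 248 UMIs) over all nuclei of the room air library, 5.44 CPM (5.02 to 5.88; 630 UMIs) in the smoke library and 5.03 CPM (3.87 to 6.42; 64 UMIs) in the aneurysm library. The labels do not say which part of the gene is disrupted, and a 3' tag outside that part checks nothing. Xist, which is transcribed from the inactive X chromosome of females, was at 0.190, 0.147 and 0.393 CPM in room air, smoke and aneurysm. Y-linked Uty was at 278.1, 265.1 and 265.5 CPM, and Y-linked Ddx3y at 83.7, 79.2 and 103.1 CPM.

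Macrophage-like nuclei made up 44.1% (43.2 to 45.0) of the room air library, 42.8% (42.0 to 43.7) of the smoke library and 13.5% (12.6 to 14.4) of the aneurysm library. Smooth muscle-like nuclei made up 3.99%, 3.77% and 2.63%, fibroblast-like nuclei 4.41%, 4.56% and 12.9% (smoke over room air 1.03, but 0.389 with libraries clustered one by one), and endothelial-like nuclei 14.6%, 11.7% and 17.4%. Adipocyte-like nuclei, whose markers include Adipoq and Plin1, took 0.336%, 1.49% and 21.9%. Dendritic-like nuclei took 5.93%, 6.53% and 0.245%, T or NK-like nuclei 3.05%, 5.41% and 0.228%, and B-like nuclei 2.32%, 2.33% and 0.105%. Lymphatic endothelial-like nuclei took 0.263%, 0.479% and 1.21%, neuron-like nuclei 0.0998%, 0.143% and 0.702%, and Schwann-like nuclei 0.0454%, 0.107% and 0.631%. The ratio of aneurysm over smoke was 4.91 for neuron-like nuclei, but 0.912 with libraries clustered one by one, and 5.89 for Schwann-like nuclei, but 0.977 at a minimum of 1000 UMIs. Striated muscle-like nuclei numbered 1, 16 and 3. The anti-nucleus bead sort, the minimum of 500 UMIs and the depth gap between libraries can all set these shares.

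Unnamed clusters held 20.8%, 20.5% and 28.6% of nuclei. Cluster 2, led by Grin2a, scored alike for fibroblast and smooth muscle markers and held 7.06%, 6.74% and 16.3%. Cluster 6, shallow and led by Gm48099, Lars2 and Cmss1, scored best for macrophage markers and held 6.71%, 4.44% and 8.59%. Cluster 9, led by Cemip, Tgfb2 and Notch3, scored best for smooth muscle markers and held 3.72%, 3.83% and 2.93%. Cluster 13, led by Pkhd1l1, scored best for endothelial markers and held 2.49%, 3.56% and 0.438%. Cluster 21, led by Igkc, Tagln and Rplp1, held 0.807%, 1.74% and 0.351%. Cluster 29 held 0.0363% and 0.207%, and 0 of 5702 nuclei of the aneurysm library, a share of up to 0.0647%.

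**Figure D1:**
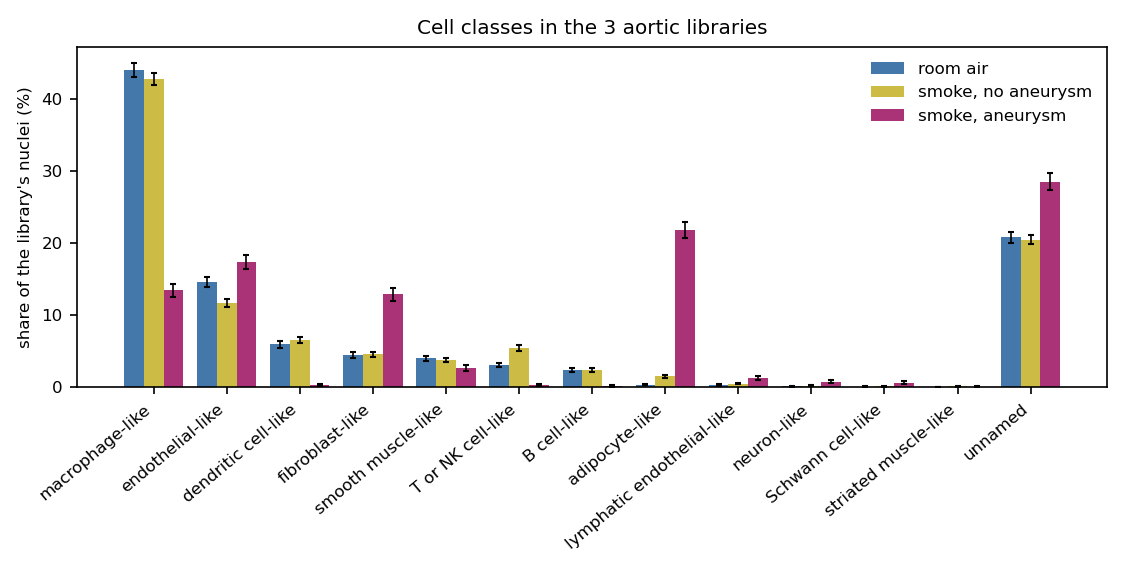
Share of each library's nuclei (percent, vertical axis) in each named class and in unnamed clusters, as bars for the room air, smoke and aneurysm libraries, with exact 95% binomial intervals that cover counting error only. Macrophage-like nuclei stand at 44.1%, 42.8% and 13.5% and adipocyte-like nuclei at 0.336%, 1.49% and 21.9%.

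The comparison of the smoke library with the room air library asks what accompanies smoke exposure without an aneurysm. Macrophage-like nuclei took nearly the same share of both libraries (ratio 0.971, 0.935 to 1.01), while T or NK-like nuclei took 1.78 times the share (1.56 to 2.03) in the smoke library, with 2.74 times at a minimum of 1000 UMIs, 1.41 times with no filter and 1.39 times without the mitochondrial limit. Within macrophage-like nuclei, the resident macrophage list was at a median log2 ratio of 0.44 and the list of immediate early and heat shock genes (handling stress) at 0.51, with 7 of 15 and 5 of 13 members at least 1.5-fold higher. Acod1, the enzyme that makes itaconate, was 7.78-fold lower (6.92 to 8.76). In endothelial-like nuclei the endothelial activation, interferon and handling stress lists were higher (0.62, 0.62 and 0.79), with Sele at 2.27-fold (2.03 to 2.53) and Cxcl10 at 5.87-fold (4.04 to 8.79). The matrix protease list was higher in fibroblast-like nuclei (0.68, and 0.18 to 0.45 under 6 alternatives), with Mmp3 2.26-fold higher (2.02 to 2.53).

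Macrophage-like nuclei numbered 4861 in room air and 5997 in smoke, with 33698951 and 56700305 UMIs and medians of 4981 and 7332. Clusters 0, 1, 4 and 5 held 29.5%, 24.5%, 16.5% and 22.2% of them in room air and 24.6%, 29.0%, 23.1% and 14.9% in smoke. The resident macrophage list had a median log2 ratio of 0.44 (0.38 to 0.74), percentile 100, with 7 of 15 measured members at least 1.5-fold higher and 0 lower. Examples are the haemoglobin scavenger receptor Cd163 at 2.85 and 9.75 CPM and the transglutaminase subunit F13a1 at 79.2 and 132.9 CPM in room air and smoke. Cluster 17, which both help define, held 1.87% and 3.22% of the class, and within it Cd163 was at 292.7 and 522.7 CPM but F13a1 at 6315 and 5446 CPM, with the list at 0.55. The handling stress list was at 0.51 (0.39 to 0.60), percentile 100, with 5 of 13 members higher and 1 lower (Hspa1b), and with Fos at 128.8 and 253.6 CPM, Dusp1 at 75.8 and 134.3 CPM and Atf3 at 313.2 and 488.0 CPM. The lipid-associated list, which holds the lipid receptor Trem2, was at 0.15 (0.14 to 0.17), percentile 99.95, with 1 of 18 members at least 1.5-fold higher: Fabp5, a fatty acid carrier, at 94.0 and 157.2 CPM. Gpnmb of that list was at 2739 and 3232 CPM. The matrix protease list was at 0.21 (0.077 to 0.26), percentile 99.87, with 1 of 18 members higher and 1 lower; the macrophage elastase Mmp12, among the genes that define cluster 0, was at 1009 and 976.6 CPM. Without genes below the other nuclei, the list was at 0.025.

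The inflammatory list stood at 0.12 (0.080 to 0.23), percentile 96.2, with 3 of 16 members higher and 2 lower. The neutrophil attractant Cxcl2 was at 46.9 and 96.6 CPM and the lipopolysaccharide co-receptor Cd14 at 19.9 and 40.7 CPM, while Tnf was at 12.6 and 10.1 CPM. The interferon list was at 0.28 (0.088 to 0.50), percentile 99.1, with 5 of 15 members higher and 2 lower; it was below 0 within cluster 0 (-0.060), within cluster 17 (-0.045) and without genes below the other nuclei (-0.15). Proliferation genes were at 0.14 (0.078 to 0.23), percentile 91.5, and protease inhibitors at 0.041 (0.014 to 0.31), percentile 53.4. MHC class II genes were at 0.016 (-0.021 to 0.19), percentile 63.9, cholesterol genes at -0.0038 (-0.097 to 0.25), percentile 33.6, aryl hydrocarbon receptor targets at -0.00039 (-0.21 to 0.20), percentile 36.3, over 4 members, and NRF2 targets at -0.11 (-0.26 to 0.0012), percentile 5.20. Haem oxygenase Hmox1, an NRF2 target, was at 32.7 and 17.8 CPM.

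Of the genes named by rule in macrophage-like nuclei, those higher in smoke were Cd209b (2 against 53 UMIs, 15.8-fold, 4.15 to 133.4), Xlr3b (7.73-fold), Cd163 (3.42-fold, 2.75 to 4.30), the chemokine Pf4 (3.90-fold), the secreted Wnt inhibitor Sfrp5 (4.24-fold), the stromelysin Mmp10 (3 against 39 UMIs, 7.73-fold, 2.46 to 39.1) and Cenpx (3.28-fold). Cluster 17 held 50 of the 53 Cd209b UMIs and 530 of the 553 Cd163 UMIs of the smoke library, and Cd163 is among the genes that define it. Lower in smoke were Acod1, Tmem267 (5.14-fold), the interferon-induced GTPase Gbp2 (4.82-fold, 4.13 to 5.64), Hspa1b (5.50-fold), Tchh (4.57-fold), the interleukin-31 receptor subunit Il31ra (3.38-fold, 3.19 to 3.59) and the chemokine Cxcl9 (4.56-fold). Of the room air UMIs, a single nucleus held 50 of 98 for Hspa1b, 82 of 209 for Tchh and 36 of 84 for Cxcl9. Tmem267 is among the genes that define cluster 0. Within cluster 0 alone, Pf4 was lower and Cxcl9 higher in smoke (log2 -0.47 and 2.55).

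Endothelial-like nuclei numbered 1611 and 1640, with 64.3% and 65.2% in cluster 3, which Bmp6 and Edn1 help define. The endothelial activation list was at 0.62 (0.49 to 0.68), percentile 100, with 7 of 12 members at least 1.5-fold higher and 0 lower. Vcam1, which binds leukocyte integrins, was at 217.1 and 334.1 CPM, Icam1 at 44.0 and 71.5 CPM and the shear-responsive factor Klf2 at 113.0 and 262.3 CPM. Alongside it, the handling stress list was at 0.79 (0.71 to 0.84), percentile 100, with 10 of 13 members higher, among them Egr1 at 218.0 and 358.3 CPM. The interferon list was at 0.62 (0.47 to 0.97), percentile 99.9, with 9 of 15 members higher and 0 lower. Aryl hydrocarbon receptor targets were at 0.42 (0.049 to 0.56), percentile 87.1, over 5 members, with Cyp1b1 at 44.4 and 59.4 CPM, and NRF2 targets were at 0.054 (-0.030 to 0.33), percentile 26.2. By rule, the glutamate transporter Slc1a1 was higher in smoke (0 against 60 UMIs, at least 16.8-fold, bound 13.2, 54 of them in cluster 16), as was Lsamp (7.97-fold). The Lsamp ratio rested on cluster 16 (1121 of 1150 UMIs) and turned below 1 at a minimum of 1000 UMIs, with 15 principal components, at resolution 2 and with libraries clustered one by one (log2 -0.049, -0.042, -0.28 and -0.49). Sgcz (8.46-fold) and Tenm2 (8.61-fold) were lower, with at most 142 UMIs in either library.

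Smooth muscle-like nuclei numbered 440 and 528, with 389 and 472 of them in cluster 11. Their matrix protease list was at 0.47 (0.14 to 0.57), percentile 100, with 6 of 16 members higher and 1 lower. It was at 0.058 without the highest Scrublet scores, 0.10 with no filter and 0.11 at resolution 0.5, but at 1.02 with libraries clustered one by one. The metalloprotease Adamts1 was at 70.4 and 152.6 CPM, and the collagenase Mmp13 was 13.3-fold higher (2 against 48 UMIs, 3.50 to 113.3). Contractile genes were at 0.10 (0.064 to 0.15), percentile 96.3, with smooth muscle myosin Myh11 at 1818 and 2089 CPM and its activator Myocd at 643.2 and 450.8 CPM. Genes of modulated smooth muscle were at 0.099 (-0.012 to 0.14), percentile 90.1, and elastic fibre genes at 0.15 (-0.16 to 0.26), percentile 89.4, with elastin, Eln, at 3432 and 2364 CPM. Protease inhibitors were at 0.040 (percentile 60.5; 0.47 in thinned nuclei), aryl hydrocarbon receptor targets at 0.074 (percentile 44.8, 3 members), NRF2 targets at 0.092 (percentile 48.5), handling stress genes at 0.17 (percentile 96.2) and proliferation genes at -0.14 (percentile 3.24; 0.59 with 15 principal components). The genes named by rule rested on few nuclei. Ptprn2 (0 against 106 UMIs, at least 19.6-fold higher in smoke, bound 15.7) had 104 UMIs in 1 nucleus, Cfap61 (3 against 98, 18.2-fold, 6.03 to 89.6) had 96 in 1, Il1rapl2 (2 against 77, 21.4-fold, 5.73 to 179.8) had 34 in 1 and Ntng1 (0 against 32, at least 5.93-fold, bound 4.55) had 26 in 1. Lower in smoke were the thyroid hormone deiodinase Dio2 (21.6-fold, 61 of 72 UMIs in 1 nucleus), Moxd1 (19.3-fold, 17 of 43 in 1), Ctnna2 (16.6-fold, 21 of 46 in 1) and the IGFBP protease Pappa (8.93-fold, 5.96 to 13.8, 144 against 29 UMIs in room air and smoke). Cfap61 was lower in smoke without the mitochondrial limit (log2 -1.54), and Dio2 higher without the highest Scrublet scores (1.16).

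Fibroblast-like nuclei numbered 486 and 639, with 95.9% and 93.9% of them in cluster 7. The matrix protease list was at 0.68 (0.46 to 0.76), percentile 100, with 9 of 16 members higher and 1 lower, and at 0.20 without genes below the other nuclei. Adamts1 was at 148.7 and 251.0 CPM. Mmp12, which was below its level in the other nuclei, was at 88.6 and 155.8 CPM. Protease inhibitors were at 0.56 (0.31 to 0.67), percentile 99.9 (0.10 with libraries clustered one by one), with Timp2 at 218.5 and 321.3 CPM. The collagen list was at 0.25 (0.13 to 0.39), percentile 98.6, with 3 of 15 members higher, and was below 0 under 4 alternatives (-0.022 to -0.82); Col1a1 was at 248.6 and 280.0 CPM. The fibroblast inflammatory list was at 0.19 (-0.11 to 0.39), percentile 90.1 (1.16 with libraries clustered one by one), with complement C3 at 345.9 and 555.9 CPM and the alarmin Il33 at 249.1 and 164.2 CPM. Elastic fibre genes were at -0.0055 (percentile 26.7), NRF2 targets at -0.12 (percentile 4.83) and handling stress genes at 0.20 (percentile 97.6), the last pair at 0.33 and 1.46 with libraries clustered one by one, and proliferation genes at 0.69 (percentile 91.5, 6 members). With 2 aryl hydrocarbon receptor targets measured, no median was taken. By rule, Cnksr2 (0 against 79 UMIs, at least 13.5-fold, bound 10.7), Ntng1 (0 against 61, at least 10.4-fold, bound 8.23), Adgrb3 (1 against 62, 31.8-fold, 5.51 to 1277) and Tenm2 (9.85-fold) were higher in smoke, each in at most 15 nuclei, of which 1 held 49, 21, 42 and 56 UMIs in that order. Pde8b (7.79-fold, 29 of 32 UMIs in 1 nucleus), the phosphate hormone Fgf23 (4.51-fold, in 10 nuclei), Stk32a (3.49-fold) and Pde1c (3.14-fold) were lower, the last pair not with libraries clustered one by one (log2 0.11 and 0.12).

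T or NK-like nuclei numbered 336 in room air and 758 in smoke, at medians of 985.5 and 1743.5 UMIs, so that depth and the minimum of 500 UMIs can set their share. In the smoke library the T cell state list was at -0.20 (-0.66 to 0.095), percentile 7.43, with 1 of 11 members higher and 4 lower. Tox, which marks repeatedly stimulated T cells, was at 3795 and 2116 CPM, the interleukin-2 receptor chain Il2ra at 110.4 and 50.9 CPM and the checkpoint receptor Ctla4 at 213.1 and 126.4 CPM. Proliferation genes were at 0.38 (-0.066 to 0.98), percentile 86.3, and below 0 with no filter and without the mitochondrial limit (-0.084 and -0.072), with Mki67 at 41.9 and 81.2 CPM (22 and 158 UMIs).

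The comparison of the aneurysm library with the smoke library asks what goes with an aneurysm among smoke-exposed mice, and the series is about plaque macrophages in that setting. Macrophage-like nuclei took 0.315 times the share (0.291 to 0.339) in the aneurysm library, and dendritic-like, T or NK-like and B-like nuclei 0.0376, 0.0421 and 0.0452 times. Fibroblast-like nuclei took 2.82 times (2.54 to 3.15; 1.87 with 15 principal components, 5.79 with libraries clustered one by one) and adipocyte-like nuclei 14.7 times the share (12.7 to 17.1). Macrophage-like nuclei of the aneurysm library had higher resident genes and lower lipid-associated genes, such as Gpnmb at 2.83-fold (2.70 to 2.96). The resident gene F13a1 was 12.7-fold higher (12.1 to 13.3) over the class; it helps define cluster 17, and within that cluster it was at 6315, 5446 and 4744 CPM in room air, smoke and aneurysm. In endothelial-like nuclei the interferon response list was at -0.68, with 9 of 15 members at least 1.5-fold lower.

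Over wall and immune classes alone, macrophage-like nuclei were 55.5% of the smoke library and 28.7% of the aneurysm library (ratio 0.517), and the fibroblast-like ratio was 4.64. The smooth muscle-like ratio (0.698, 0.578 to 0.838) turned above 1 under 6 alternatives (1.02 to 2.22). The endothelial-like ratio (1.49, 1.37 to 1.61) turned to 0.726 with 15 principal components.

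Macrophage-like nuclei numbered 768 in the aneurysm library, with 1613891 UMIs and a median of 1567. Cluster 17, defined by F13a1, Cd163 and Mrc1, held 44.1% of them (40.6 to 47.7), against 3.22% (2.79 to 3.70) in smoke and 1.87% (1.51 to 2.29) in room air. Clusters 0, 1, 4 and 5 held 23.4%, 17.3%, 3.78% and 7.29%, the proliferating cluster 19 2.47% against 4.74% in smoke, and cluster 26 held 57, 29 and 12 nuclei of room air, smoke and aneurysm. The largest clusters of the class thus differ: 17, 0 and 1 in aneurysm, and 1, 0 and 4 in smoke. With 1 library per group, a cluster held mostly by 1 library can reflect that library and not a cell type. The resident list was at 2.21 (1.94 to 2.29), percentile 100, with 14 of 15 members higher and 0 lower, and several of its members define cluster 17. It was at 1.63 over members expected at 5 UMIs, at -0.21 within cluster 17 alone and at 0.078 within cluster 0. Lyve1, a hyaluronan receptor, was at 1.57 and 42.8 CPM in smoke and aneurysm, Timd4, a phosphatidylserine receptor, at 1.15 and 27.9 CPM, and Igf1, the member not counted as higher, at 944.7 and 689.0 CPM.

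**Figure D2:**
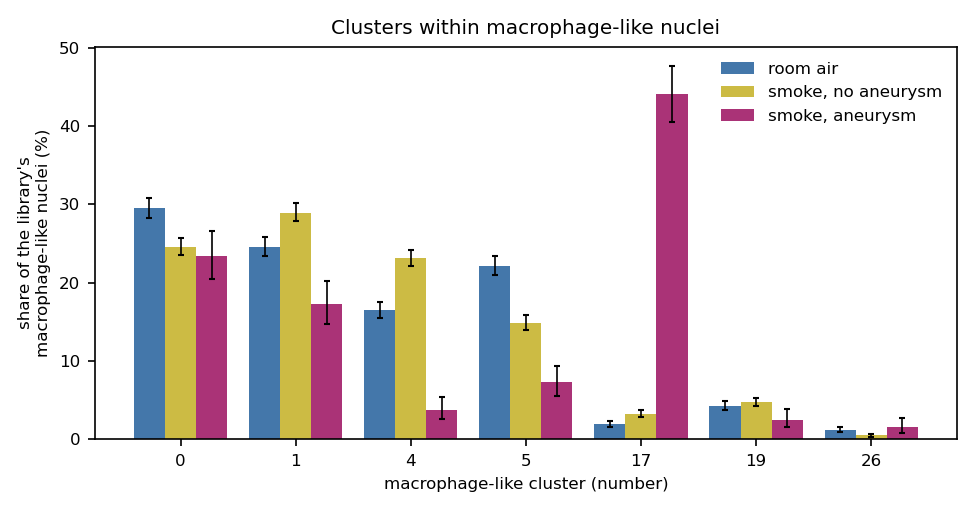
Share of each library's macrophage-like nuclei (percent, vertical axis) in clusters 0, 1, 4, 5, 17, 19 and 26, as bars for the room air, smoke and aneurysm libraries, with exact 95% binomial intervals that cover counting error only. Cluster 17 holds 1.87%, 3.22% and 44.1%.

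The lipid-associated list in macrophage-like nuclei was at -0.91 (-0.99 to -0.82), percentile 0, with 0 of 18 members higher and 15 lower. Fabp5 was at 157.2 and 50.8 CPM in smoke and aneurysm, the lysosomal lipase Lipa at 389.0 and 185.9 CPM, the cholesterol exporter Abcg1 at 1121 and 551.5 CPM and Trem2 at 94.8 and 51.4 CPM. Within cluster 0 the list was at -0.46 and within cluster 17 at -1.01. Proliferation genes were at -0.80 (-1.08 to -0.49), percentile 0.020, with 9 of 12 lower and Top2a at 30.7 and 16.7 CPM. Within cluster 0 the list was at 1.14, but over 7 members with at most 8 UMIs each in aneurysm. With the macrophage-like clusters weighted as in the smoke library it turned to 0.30 (0.029 to 0.64). As 5 of its members help define these clusters, the class value may reflect their mix. Interferon genes were at -0.56 (-0.92 to -0.36), percentile 0.54, with 7 of 15 lower and 1 higher, such as Rsad2 at 22.8 and 9.29 CPM; the list was at -1.25 with libraries clustered one by one and -0.15 within cluster 0. Matrix proteases were at -0.032 (-0.28 to 0.14), percentile 47.3, with 6 of 18 higher and 8 lower. Mmp12 was at 976.6 and 436.2 CPM and the elastolytic cathepsin Ctss at 904.1 and 341.4 CPM, whereas the gelatinase Mmp9 was 58.6-fold higher (27.3 to 131.4, 12 against 20 UMIs). Without genes below the other nuclei, the protease list was at -0.85, and within cluster 17 at -0.73 (-0.26 over members expected at 5 UMIs).

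Inflammatory genes in these nuclei were at -0.12 (-0.41 to 0.053), percentile 16.6, with 5 of 16 higher and 6 lower. Tnf was 8.11-fold lower (2.24 to 67.2, 570 against 2 UMIs) and Cxcl2 2.89-fold lower (2.21 to 3.85), while the NF-kB inhibitor Nfkbia was 2.05-fold higher (1.76 to 2.37). This list was at -0.67 without genes below the other nuclei, -0.76 in thinned nuclei and -0.65 within cluster 17. MHC class II genes were at -0.21 (-0.40 to -0.023), percentile 11.7, and at 0.17 without genes below the other nuclei, but at -1.02 in thinned nuclei, -1.06 within cluster 0 and -1.72 within cluster 17 (-0.28 and -1.56 over members expected at 5 UMIs). Protease inhibitors were at 0.33 (-0.25 to 0.53), percentile 82.8 (0.78 with libraries clustered one by one). Handling stress genes were at 0.14 (percentile 79.2; -0.29 within cluster 17), cholesterol genes at 0.067 (percentile 47.8; -0.48 within cluster 0), aryl hydrocarbon receptor targets at 0.58 (percentile 81.2; 4 members, of which only Tiparp, at -0.80, had over 10 UMIs in aneurysm) and NRF2 targets at -0.025 (percentile 33.6; -0.52 within cluster 0 and 0.46 within cluster 17). Median-of-ratios and TMM scaling lowered all ratios of this class by 0.15 and 0.15 log2 units against total-count scaling. In the comparison of aneurysm with room air they lowered them by 0.16 and 0.15.

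**Figure D3:**
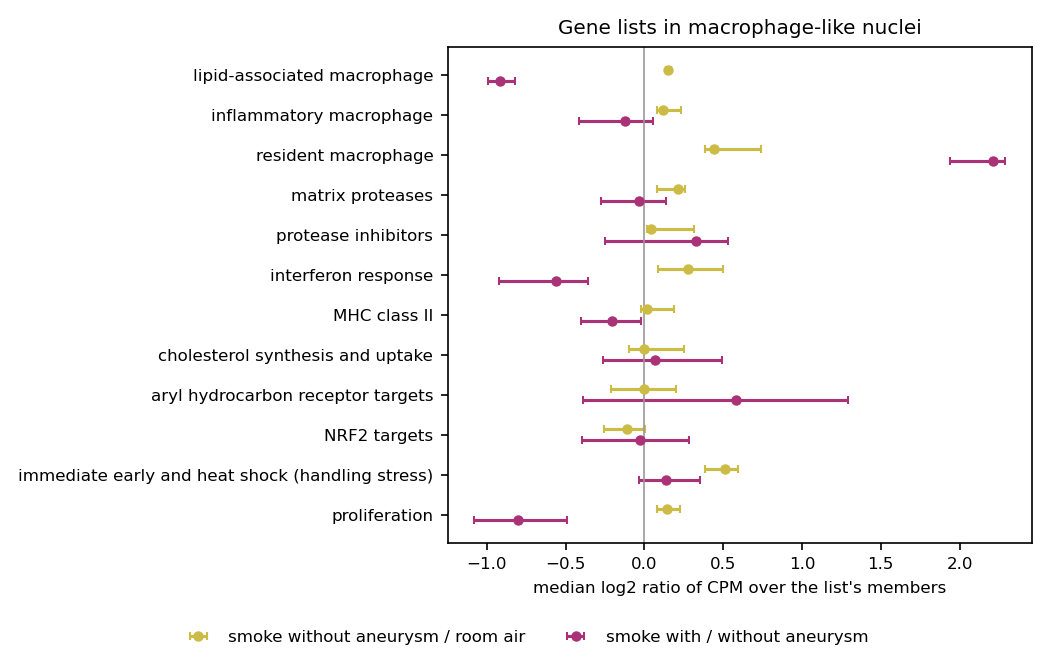
Median log2 CPM ratio of each fixed list in macrophage-like nuclei (horizontal axis) for smoke over room air and aneurysm over smoke, as points with counting intervals from 1000 Poisson redraws. For aneurysm over smoke the resident list stands at 2.21 and the lipid-associated list at -0.91.

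Named by rule, the genes higher in macrophage-like nuclei of the aneurysm library were the cadherin Cdh6 (523.5-fold, 276.8 to 1114), the B cell attractant Cxcl13 (238.1-fold, 144.5 to 415.2), the sarcomere protein titin, Ttn (118.9-fold, 105.1 to 134.7), the complement inhibitor Cd55 (84.6-fold, 68.5 to 105.1), the collagen VI chain Col6a5 (58.9-fold), Ms4a8a (40.1-fold) and the acute-phase protein Saa3 (41.7-fold). Cluster 17 held nearly all of their UMIs, such as 147 of 149 for Cdh6 and 1102 of 1130 for Ttn. Within cluster 17, Cdh6 was at 0, 0 and 258.5 CPM in room air, smoke and aneurysm (3 counts being 10.3 and 2.96 CPM in the first pair), Cxcl13 at 6.89, 9.86 and 211.0 CPM and Ttn at 10.3, 8.88 and 1938 CPM. Lower in the aneurysm library were Bcar3 (4.66-fold, 4.02 to 5.44), Insyn2b (9.03-fold), Adgrg3 (6.79-fold), Cytip (5.38-fold), Lrrc4 (7.19-fold) and the laminin receptor subunit Itga6 (3.77-fold). Cytip is among the genes that define cluster 4.

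A UMI of Mmp12 was found in 56.0%, 63.5% and 23.3% of macrophage-like nuclei of room air, smoke and aneurysm, and in 28.7%, 29.6% and 17.4% after thinning to 1000 UMIs. Endothelial-like nuclei, which should lack it, gave 32.3%, 39.5% and 5.65%, and 8.89%, 10.1% and 3.41% after thinning. For Gpnmb the macrophage-like shares were 83.9%, 86.5% and 44.0% (thinned 66.0%, 65.0% and 39.7%), and the endothelial-like shares 47.0%, 60.1% and 10.2% (thinned 17.1%, 17.4% and 5.18%). For F13a1 they were 6.91%, 10.6% and 41.9% (thinned 3.88%, 5.11% and 35.3%), against endothelial-like shares of 3.41%, 5.43% and 4.23% (thinned 0.790%, 1.25% and 2.32%). Thinning left out 72, 28 and 193 macrophage-like and 92, 35 and 258 endothelial-like nuclei. Median depths were 4981, 7332 and 1567 UMIs in the former and 6823, 9753.5 and 1819.5 UMIs in the latter.

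Smooth muscle-like nuclei numbered 150 in the aneurysm library, with 396702 UMIs against 4777897 in smoke. The modulated smooth muscle list was at -0.77 (-1.05 to -0.59), percentile 0, with 0 of 18 members higher and 12 lower, but was at 0.078 at resolution 2, -0.026 with 15 principal components and -0.074 with libraries clustered one by one. Lum, a small proteoglycan, was at 49.0 and 12.6 CPM in smoke and aneurysm, and fibronectin, Fn1, at 1240 and 778.9 CPM. The contractile list was at 0.25 (0.14 to 0.42), percentile 98.8, with 6 of 19 higher and 1 lower, and was below 0 at resolutions 0.5 and 2 and with 15 principal components (-0.19, -0.38 and -0.46). Myocd was at 450.8 and 1346 CPM and smooth muscle actin, Acta2, at 820.0 and 1097 CPM. In the unnamed cluster 9 the contractile and modulated lists were at 0.31 and -0.28. Matrix proteases were at -1.05 (-1.28 to -0.31), percentile 0, with 10 of 16 lower and 1 higher; Ctsb, below its level in the other nuclei, was at 241.3 and 83.2 CPM. Protease inhibitors were at -0.34 (percentile 5.91; -0.86 in thinned nuclei), elastic fibre genes at -0.18 (percentile 21.3; -0.73 in thinned nuclei), NRF2 targets at -0.51 (percentile 11.4; 0.17 over members expected at 5 UMIs, -0.94 with libraries clustered one by one), handling stress genes at -0.091 (percentile 29.1; -0.53 to -0.74 under 5 alternatives) and proliferation genes at -0.31 (percentile 7.26; -0.91 to -1.59 under 3 alternatives). With 2 aryl hydrocarbon receptor targets measured, no median was taken.

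By rule, Rgs6, which restrains G protein signalling, was 12.9-fold higher (9.86 to 17) in smooth muscle-like nuclei of the aneurysm library, Il1rapl1 13.7-fold (47 of 65 UMIs in 1 nucleus), Adamtsl1 7.36-fold and the matrix glycoprotein Sparcl1 6.32-fold (4.71 to 8.43; 26 of 74 UMIs in 1 nucleus), each in at most 23 nuclei. Lower were the hyaluronan-degrading Cemip (15.7-fold, 6.12 to 57.9; 205 of 758 UMIs in 1 nucleus and 537 in cluster 25), which also leads cluster 9, Kctd8 (189 against 0 UMIs, at least 5.23-fold, bound 4.21), the transcription factor Hlf (254 against 1, 21.1-fold, 3.75 to 836.2) and Ano3 (234 against 1, 19.4-fold, 3.45 to 770.6; 107 of the 234 in 1 nucleus). Cemip was higher in the aneurysm library, by 0.90 log2 units, with libraries clustered one by one.

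Fibroblast-like nuclei numbered 735 in the aneurysm library, of which cluster 7 held 74.0% and cluster 22, defined by Cd55 and Adamts5, 26.0% against 6.10% in smoke. Fibrillin-1, Fbn1, was 2.87-fold higher (2.69 to 3.05) and complement C4b 2.24-fold higher (1.98 to 2.53). Cxcl12 was 2.29-fold lower (1.94 to 2.72) and C3 2.10-fold lower (1.88 to 2.35). These ratios are over the whole class, so the larger share of cluster 22 can set them. The matrix protease list was at -1.23 (-1.49 to -0.54), percentile 0, with 10 of 17 lower and 4 higher, and turned to 0.33 without genes below the other nuclei; it was at -0.13 to -0.50 under 5 alternatives and at -0.82 within cluster 7. Mmp3 was at 444.2 and 169.2 CPM in smoke and aneurysm, and the gelatinase Mmp2 at 85.2 and 181.6 CPM. The collagen list was at -0.41 (-0.48 to -0.22), percentile 0.64, with 6 of 15 lower and 3 higher. It was at -0.25 within cluster 7 and turned to 0.25 with libraries clustered one by one. Col1a1 was at 280.0 and 180.3 CPM. Protease inhibitors were at -0.47 (percentile 2.46; -1.28 with 15 principal components). Handling stress genes were at -0.34 (percentile 2.25), but at 0.10 with 15 principal components and -1.26 with libraries clustered one by one. Proliferation genes were at -1.87 (percentile 0.545, 5 members), elastic fibre genes at 0.057 (percentile 62.5), inflammatory genes at -0.10 (percentile 20.5; 0.47 to 1.09 under 5 alternatives, -0.39 with libraries clustered one by one) and NRF2 targets at 0.080 (percentile 56.6), with 2 aryl hydrocarbon receptor targets measured and no median.

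Named by rule, Krt25 (1 against 112 UMIs, 51 of them in 1 nucleus, 297.0-fold, 52.2 to 11830), the tolloid-like protease Tll2 (70.4-fold, 36.5 to 155.9), the nuclear receptor Rorb (79.0-fold, 33.1 to 246.9) and Mgam (1 against 55, 145.8-fold, 25.1 to 5864) were higher in fibroblast-like nuclei of the aneurysm library, almost wholly in cluster 22. The hedgehog inhibitor Hhip (463 against 1 UMIs, 174.6-fold, 31.2 to 6912), Cdh12 (21.2-fold) and Nkain2 (10.2-fold) were lower, and cluster 7 held most of their smoke UMIs.

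Endothelial-like nuclei numbered 992 in the aneurysm library, with 33.6% in cluster 3, 24.8% in cluster 8 and 41.6% in cluster 16, which Adgrl4 helps define, against 65.2%, 23.8% and 10.98% in smoke. The interferon list was at -0.68 (-1.39 to -0.50), percentile 0.81, with 9 of 15 lower and 0 higher, and at -1.35 within cluster 3, -0.76 within cluster 16 and -1.80 with 15 principal components. The chemokine Cxcl10 was at least 13.02-fold lower (224 against 0 UMIs, bound 10.5) and Gbp2 4.01-fold lower (2.64 to 6.38). The activation list was at -0.16 (-0.24 to -0.096), percentile 3.33, with 5 of 12 lower and 1 higher. It was at -0.35 (-0.49 to -0.18) within cluster 3 and -0.056 (-0.58 to 0.24) within cluster 16. Over the class, Vcam1 was at 334.1 and 137.8 CPM, Sele at 71.2 and 27.0 CPM but Klf4 at 129.1 and 236.7 CPM. Handling stress genes were at -0.23 (percentile 1.09), aryl hydrocarbon receptor targets at -0.56 (percentile 13.9, 5 members) and NRF2 targets at -0.23 (percentile 14.9). By rule, the serotonin receptor Htr2a (17.2-fold, 10.2 to 30.1) and Igfbp3 (18.6-fold, 9.56 to 39.1) were higher, mostly in cluster 16, and the growth factor midkine, Mdk, was 10.98-fold lower (5.00 to 30.1).

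**Figure D4:**
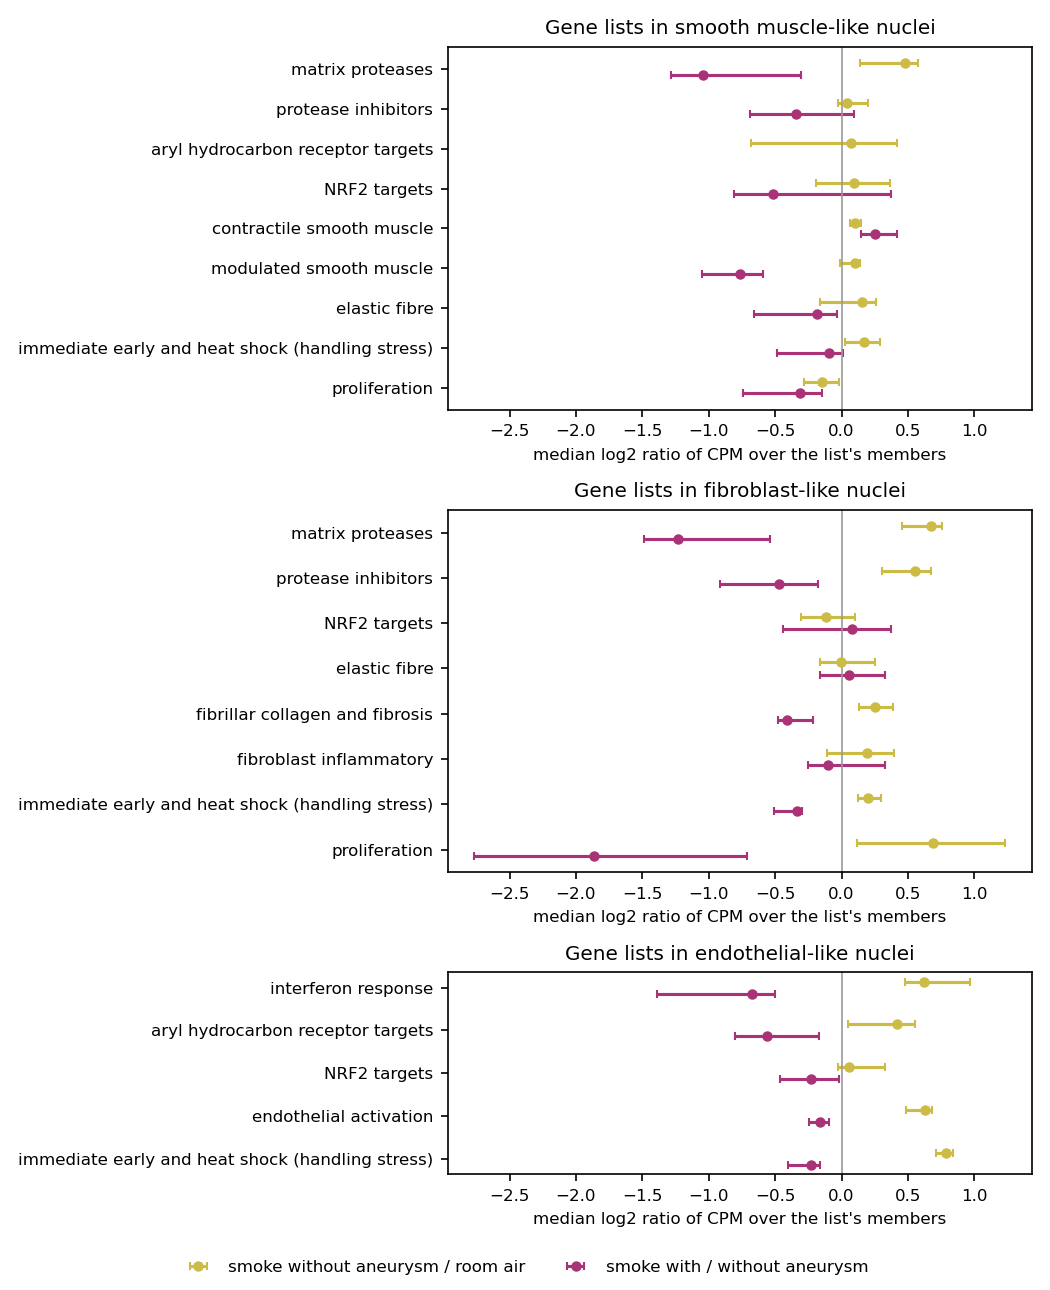
Median log2 CPM ratio of each fixed list in smooth muscle-like, fibroblast-like and endothelial-like nuclei (horizontal axis) for smoke over room air and aneurysm over smoke, as points with counting intervals from 1000 Poisson redraws. In endothelial-like nuclei the interferon list stands at 0.62 and -0.68.

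The comparison of the aneurysm library with the room air library sets smoke with an aneurysm against neither. Macrophage-like nuclei took 0.305 times the share (0.283 to 0.330), or 0.510 times over wall and immune classes alone, and the resident list was at 2.86 (2.23 to 3.03), percentile 100, with 14 of 15 members higher. It was at 1.79 over members expected at 5 UMIs, 0.57 within cluster 17 and -0.16 within cluster 0 (0.13 over such members). The lipid-associated list was at -0.68 (-0.82 to -0.59), percentile 0, with 10 of 18 lower and 0 higher, but at -0.25 within cluster 0 and -0.23 (-0.44 to 0.0078) within cluster 17. Handling stress genes were at 0.46 (0.28 to 0.80), percentile 99.6, with 6 of 13 higher and 2 lower, and at 0.095 in thinned nuclei and 0.013 within cluster 17. Interferon genes were at -0.72 (-0.99 to -0.13), percentile 0.010, with 8 of 13 lower and 1 higher. Proliferation genes were at -0.65 (-0.95 to -0.34), percentile 0.030, with 7 of 12 lower and 0 higher, and at 0.65 within cluster 0, over 6 members with at most 8 UMIs each in aneurysm. The inflammatory list was at 0.029 (-0.31 to 0.13), percentile 45.8 (-0.41 in thinned nuclei and -0.49 within cluster 0). Matrix proteases were at -0.26 (percentile 3.01), protease inhibitors at 0.40 (percentile 81.3; -0.14 in thinned nuclei) and MHC class II genes at 0.19 (percentile 85.4; -0.58 in thinned nuclei, -0.91 within cluster 0 and -1.23 within cluster 17). Cholesterol genes were at 0.046 (percentile 43.7), aryl hydrocarbon receptor targets at 0.48 (percentile 78.4, 4 members; Tiparp at -0.70) and NRF2 targets at -0.052 (percentile 28.0; -0.68 within cluster 0 and 0.94 within cluster 17). Named by rule, Cxcl13 (636.9-fold, 242.5 to 2375), Cdh6 (345.7-fold), Lyve1 (205.8-fold, 94.7 to 531.0) and Cd55 (110.3-fold) were higher in macrophage-like nuclei of the aneurysm library. The hepatocyte growth factor receptor Met (5.64-fold), Bcar3 (4.44-fold) and Itga6 (3.25-fold) were lower.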

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

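The mitochondrial limit was set before the result was seen, and the alternative without it was chosen afterwards. Barcodes at or above 5% of UMIs on mitochondrial genes stood outside every comparison and made up 22.3% (21.4 to 23.3; 1641 of 7348) of the aneurysm library. In the room air library they made up 16.4% (15.8 to 17.1; 2167 of 13189), and in the smoke library 5.77% (5.41 to 6.16; 858 of 14859). The aneurysm share thus stood above that of the control library. With these barcodes included, macrophage-like nuclei took 0.275 times the share of smoke in the aneurysm library, in place of 0.315.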

How the results depend on the processing

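Leaving out the highest Scrublet scores, assigning unnamed clusters to their best-scoring class, using cluster 0 or cluster 17 alone, asking for 5 expected UMIs per list member and dropping the mitochondrial limit were chosen after seeing the data. With 1 library per group, no replicate could be left out. No paired analysis was possible because each group has 1 library. Values within their counting interval numbered 1101 for list medians, 986 for named genes, 299 for share ratios and 256 for shares. Outside it were 218, 198, 75 and 184. Besides these, 18 list medians at the extremes of the random lists, 11 named genes and 17 share ratios with intervals excluding 1 changed sign or side of 1, called reversed here; the cause was not tested. Values near 0 or 1 crossed it too without that name. The macrophage-like share ratio of aneurysm over smoke stayed below 1 in each alternative run, between 0.254 and 0.517. Depth limits the aneurysm library most, at a median of 1443 UMIs. Outside macrophages, scaling lowered ratios by over 0.1 log2 units only for aneurysm over room air. The falls were 0.12 and 0.11 in fibroblast-like and 0.14 and 0.14 in endothelial-like nuclei (median-of-ratios and TMM). Medians given here are log2 ratios of lists under short names.

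At a minimum of 1000 UMIs, share ratios of smoke over room air were 0.897 for macrophage-like, 1.29 for dendritic-like, 2.74 for T or NK-like and 1.48 for B-like nuclei. At 1000 UMIs, share ratios of aneurysm over smoke were 0.412 for macrophage-like, 2.47 for fibroblast-like, 1.32 for endothelial-like and 0.977 for Schwann-like nuclei (reversed). At 1000 UMIs, share ratios of aneurysm over room air were 0.370 for macrophage-like, 2.59 for fibroblast-like and 1.02 for endothelial-like nuclei. At 1000 UMIs, macrophage medians of aneurysm over smoke were 1.93 (resident), -0.46 (MHC class II) and -1.23 (proliferation). At 1000 UMIs, endothelial medians of aneurysm over smoke were -0.86 (aryl hydrocarbon) and -0.44 (activation). At 1000 UMIs, the reversed log2 ratio of a named gene was -0.049 for Lsamp in endothelium (smoke over room air).

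Without any filter on barcodes, share ratios of smoke over room air were 1.15 for macrophage-like, 0.9496 for endothelial-like, 0.937 for dendritic-like and 1.41 for T or NK-like nuclei. With every barcode, share ratios of aneurysm over smoke were 0.254 for macrophage-like and 1.04 for endothelial-like nuclei. With every barcode, the share ratio of aneurysm over room air was 0.993 for endothelial-like nuclei (reversed). With every barcode, macrophage medians of smoke over room air were -0.032 (MHC class II) and 0.058 (proliferation). With every barcode, macrophage medians of aneurysm over smoke were -1.08 (lipid), 0.080 (inflammatory), 2.32 (resident), -0.012 (MHC class II) and 0.36 (handling stress). With every barcode, the smooth muscle median of smoke over room air was 0.10 (protease). With every barcode, fibroblast medians of smoke over room air were 0.25 (protease), 0.30 (elastic fibre), -0.061 (collagen, reversed) and 0.34 (handling stress). With every barcode, fibroblast medians of aneurysm over smoke were -0.14 (protease) and 0.70 (inflammatory). With every barcode, the endothelial median of aneurysm over smoke was -0.065 (activation). With every barcode, the T or NK cell median of smoke over room air was -0.084 (proliferation).

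At Leiden resolution 0.5, the share ratio of smoke over room air was 0.915 for macrophage-like nuclei. At resolution 0.5, share ratios of aneurysm over smoke were 0.504 for macrophage-like and 1.51 for smooth muscle-like nuclei (reversed). At resolution 0.5, share ratios of aneurysm over room air were 0.462 for macrophage-like and 1.48 for smooth muscle-like nuclei (reversed). At resolution 0.5, the macrophage median of smoke over room air was 0.066 (inflammatory). At resolution 0.5, the macrophage median of aneurysm over smoke was 1.86 (resident). At resolution 0.5, smooth muscle medians of smoke over room air were 0.11 (protease), 0.40 (inhibitor) and 0.15 (contractile). At resolution 0.5, smooth muscle medians of aneurysm over smoke were -0.19 (contractile, reversed), -0.52 (modulated) and -0.91 (proliferation). At resolution 0.5, the fibroblast median of aneurysm over smoke was -0.29 (handling stress).

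After thinning to 1000 UMIs, share ratios of smoke over room air were 0.902 for macrophage-like, 1.31 for dendritic-like, 2.67 for T or NK-like, 1.40 for B-like and 12.99 for Schwann-like nuclei. In thinned nuclei, share ratios of aneurysm over smoke were 0.413 for macrophage-like, 1.02 for smooth muscle-like (reversed) and 2.35 for fibroblast-like nuclei. In thinned nuclei, share ratios of aneurysm over room air were 0.373 for macrophage-like, 1.04 for smooth muscle-like (reversed), 2.52 for fibroblast-like and 67.2 for Schwann-like nuclei. In thinned nuclei, macrophage medians of smoke over room air were 0.12 (lipid), 0.29 (inflammatory), 0.38 (resident), 0.65 (interferon), 0.28 (MHC class II), -0.32 (aryl hydrocarbon), -0.26 (NRF2) and 0.25 (proliferation). In thinned nuclei, macrophage medians of aneurysm over smoke were -0.59 (lipid), -0.76 (inflammatory), 1.72 (resident), -1.02 (MHC class II) and -0.080 (handling stress). In thinned nuclei, macrophage medians of aneurysm over room air were -0.46 (lipid), -0.41 (inflammatory) and 2.10 (resident). In thinned nuclei, smooth muscle medians of smoke over room air were 0.47 (inhibitor), 0.29 (modulated) and 0.42 (elastic fibre). In thinned nuclei, smooth muscle medians of aneurysm over smoke were -0.86 (inhibitor), -0.73 (elastic fibre) and -0.53 (handling stress). In thinned nuclei, fibroblast medians of smoke over room air were 0.28 (inhibitor) and 0.10 (collagen). In thinned nuclei, fibroblast medians of aneurysm over smoke were 0.45 (elastic fibre) and 0.47 (inflammatory). In thinned nuclei, endothelial medians of smoke over room air were -0.083 (NRF2), 0.72 (activation) and 0.54 (handling stress).

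With unnamed clusters assigned to their best-scoring class, share ratios of smoke over room air were 0.930 for macrophage-like, 1.10 for smooth muscle-like and 0.893 for endothelial-like nuclei. With all clusters assigned, share ratios of aneurysm over smoke were 0.467 for macrophage-like, 2.53 for fibroblast-like and 1.17 for endothelial-like nuclei. Once all clusters were assigned, share ratios of aneurysm over room air were 0.434 for macrophage-like, 2.53 for fibroblast-like and 1.04 for endothelial-like nuclei. With all clusters assigned, macrophage medians of aneurysm over smoke were 1.89 (resident) and -0.46 (MHC class II). Once all clusters were assigned, smooth muscle medians of smoke over room air were 0.32 (inhibitor) and -0.038 (handling stress). With all clusters assigned, the smooth muscle median of aneurysm over smoke was -0.50 (modulated). Once all clusters were assigned, fibroblast medians of smoke over room air were 0.18 (protease) and -0.022 (collagen, reversed). With all clusters assigned, fibroblast medians of aneurysm over smoke were -0.17 (protease), 0.77 (inflammatory) and -0.091 (handling stress). Once all clusters were assigned, the endothelial median of aneurysm over smoke was -0.087 (activation).

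With 15 principal components, share ratios of aneurysm over smoke were 0.284 for macrophage-like, 2.22 for smooth muscle-like (reversed), 1.87 for fibroblast-like and 0.726 for endothelial-like nuclei (reversed). With 15 components, share ratios of aneurysm over room air were 0.277 for macrophage-like, 2.11 for smooth muscle-like (reversed), 2.00 for fibroblast-like and 0.616 for endothelial-like nuclei (reversed). With 15 components, macrophage medians of aneurysm over smoke were 2.29 (resident) and 0.051 (MHC class II). With 15 components, the macrophage median of aneurysm over room air was -0.58 (lipid). With 15 components, smooth muscle medians of smoke over room air were -0.16 (inhibitor), -0.037 (contractile), -0.097 (modulated) and 0.59 (proliferation). With 15 components, smooth muscle medians of aneurysm over smoke were -0.46 (contractile, reversed), -0.026 (modulated) and -0.74 (handling stress). With 15 components, fibroblast medians of smoke over room air were 0.22 (protease), 0.31 (elastic fibre) and 0.028 (collagen). With 15 components, fibroblast medians of aneurysm over smoke were -0.22 (protease), -1.28 (inhibitor), -0.74 (collagen), 1.09 (inflammatory) and 0.10 (handling stress, reversed). With 15 components, endothelial medians of aneurysm over smoke were -1.80 (interferon) and -0.82 (aryl hydrocarbon). With 15 components, the reversed log2 ratio of a named gene was -0.042 for Lsamp in endothelium (smoke over room air).

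With libraries clustered one by one, share ratios of aneurysm over smoke were 0.516 for macrophage-like, 1.66 for smooth muscle-like (reversed), 5.79 for fibroblast-like, 1.65 for endothelial-like and 0.912 for neuron-like nuclei (reversed). With separate clustering, share ratios of aneurysm over room air were 0.493 for macrophage-like, 2.17 for smooth muscle-like (reversed), 2.25 for fibroblast-like, 1.07 for endothelial-like and 44.7 for adipocyte-like nuclei. With separate clustering, share ratios of smoke over room air were 1.31 for smooth muscle-like, 0.389 for fibroblast-like, 0.652 for endothelial-like and 1.47 for B-like nuclei. With separate clustering, macrophage medians of aneurysm over smoke were 1.78 (resident), 0.78 (inhibitor) and -1.25 (interferon). With separate clustering, smooth muscle medians of smoke over room air were 1.02 (protease), 0.48 (inhibitor), 0.036 (contractile), 0.44 (modulated) and 0.29 (handling stress). With separate clustering, smooth muscle medians of aneurysm over smoke were -1.32 (protease), -0.94 (NRF2), 0.020 (contractile), -0.074 (modulated), -0.66 (handling stress) and -1.59 (proliferation). With separate clustering, fibroblast medians of smoke over room air were 0.10 (inhibitor), 0.33 (NRF2), 0.27 (elastic fibre), -0.82 (collagen, reversed), 1.16 (inflammatory) and 1.46 (handling stress). With separate clustering, fibroblast medians of aneurysm over smoke were -0.28 (elastic fibre), 0.25 (collagen, reversed), -0.39 (inflammatory) and -1.26 (handling stress). With separate clustering, the endothelial median of smoke over room air was 0.39 (interferon). With separate clustering, the endothelial median of aneurysm over smoke was -0.095 (activation). With separate clustering, reversed log2 ratios of named genes were 0.90 for Cemip in smooth muscle (aneurysm over smoke), 0.11 for Stk32a in fibroblasts (smoke over room air), 0.12 for Pde1c in fibroblasts (smoke over room air) and -0.49 for Lsamp in endothelium (smoke over room air).

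Without the highest Scrublet scores, share ratios of aneurysm over smoke were 0.286 for macrophage-like, 1.69 for endothelial-like and 18.9 for adipocyte-like nuclei. Without those nuclei, the share ratio of aneurysm over room air was 1.35 for endothelial-like nuclei. Without those nuclei, smooth muscle medians of smoke over room air were 0.058 (protease), 0.038 (contractile) and -0.34 (proliferation). Without those nuclei, the fibroblast median of smoke over room air was 0.45 (protease). Without those nuclei, fibroblast medians of aneurysm over smoke were -0.50 (protease) and -0.49 (collagen). Without those nuclei, the endothelial median of smoke over room air was -0.031 (NRF2). Without those nuclei, the endothelial median of aneurysm over smoke was -0.34 (activation). Without those nuclei, the reversed log2 ratio of a named gene was 1.16 for Dio2 in smooth muscle (smoke over room air).

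Without the mitochondrial limit, share ratios of aneurysm over smoke were 0.275 for macrophage-like, 1.77 for endothelial-like and 0.0641 for dendritic-like nuclei. Without that limit, share ratios of aneurysm over room air were 0.275 for macrophage-like, 2.59 for fibroblast-like and 1.35 for endothelial-like nuclei. Without that limit, share ratios of smoke over room air were 1.09 for smooth muscle-like, 0.930 for dendritic-like and 1.39 for T or NK-like nuclei. Without that limit, the macrophage median of smoke over room air was -0.037 (MHC class II). Without that limit, smooth muscle medians of smoke over room air were 0.037 (contractile) and -0.37 (proliferation). Without that limit, fibroblast medians of smoke over room air were 0.25 (protease), 0.30 (elastic fibre) and -0.073 (collagen, reversed). Without that limit, fibroblast medians of aneurysm over smoke were -0.13 (protease) and 0.71 (inflammatory). Without that limit, the endothelial median of aneurysm over smoke was -0.32 (activation). Without that limit, the T or NK cell median of smoke over room air was -0.072 (proliferation). Without that limit, the reversed log2 ratio of a named gene was -1.54 for Cfap61 in smooth muscle (smoke over room air).

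Over wall and immune classes alone, share ratios of aneurysm over smoke were 0.517 for macrophage-like, 1.15 for smooth muscle-like (reversed), 4.64 for fibroblast-like and 2.44 for endothelial-like nuclei. Over these classes, share ratios of aneurysm over room air were 0.510 for macrophage-like, 1.10 for smooth muscle-like (reversed), 4.88 for fibroblast-like and 1.99 for endothelial-like nuclei.

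At Leiden resolution 2, share ratios of aneurysm over smoke were 2.2 for smooth muscle-like (reversed) and 1.32 for endothelial-like nuclei. At resolution 2, share ratios of aneurysm over room air were 1.98 for smooth muscle-like (reversed) and 1.01 for endothelial-like nuclei. At resolution 2, the share ratio of smoke over room air was 1.27 for B-like nuclei. At resolution 2, the macrophage median of aneurysm over smoke was 0.0089 (MHC class II). At resolution 2, smooth muscle medians of smoke over room air were -0.055 (inhibitor) and -0.069 (modulated). At resolution 2, smooth muscle medians of aneurysm over smoke were -0.38 (contractile, reversed), 0.078 (modulated, reversed), -0.59 (handling stress) and -1.44 (proliferation). At resolution 2, the endothelial median of aneurysm over smoke was -0.49 (activation). At resolution 2, the reversed log2 ratio of a named gene was -0.28 for Lsamp in endothelium (smoke over room air).

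Within cluster 0, medians of smoke over room air were 0.21 (lipid), 0.043 (inflammatory), 0.30 (resident), 0.031 (protease), -0.060 (interferon, reversed), -0.12 (MHC class II), -0.28 (aryl hydrocarbon), -0.32 (NRF2), 0.32 (handling stress) and -0.34 (proliferation). In cluster 0, medians of aneurysm over smoke were -0.46 (lipid), 0.078 (resident), 1.03 (inhibitor), -0.15 (interferon), -1.06 (MHC class II), -0.48 (cholesterol), -0.52 (NRF2) and 1.14 (proliferation, reversed). Over members expected at 5 UMIs in both libraries, they were -0.0020 (inhibitor), -0.28 (MHC class II) and -0.73 (cholesterol), and no proliferation gene qualified. In cluster 0, medians of aneurysm over room air were -0.25 (lipid), -0.49 (inflammatory) and -0.16 (resident, reversed), with -0.81 (inflammatory) and 0.13 (resident) over members expected at 5 UMIs. In cluster 0, reversed log2 ratios of named genes were -0.47 for Pf4 in macrophages (smoke over room air) and 2.55 for Cxcl9 in macrophages (smoke over room air).

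Within cluster 17, medians of smoke over room air were 0.39 (lipid), 0.40 (inflammatory), 0.36 (protease), -0.045 (interferon, reversed), 0.26 (MHC class II), 0.30 (NRF2) and 0.29 (handling stress). In cluster 17, medians of aneurysm over smoke were -1.01 (lipid), -0.65 (inflammatory), -0.21 (resident, reversed), -0.73 (protease; -0.26 over members expected at 5 UMIs), -1.72 (MHC class II), 0.46 (NRF2) and -0.29 (handling stress). In cluster 17, medians of aneurysm over room air were -0.23 (lipid), 0.29 (inflammatory) and 0.57 (resident).

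Without genes below the other nuclei, macrophage medians of smoke over room air were 0.27 (inflammatory), 0.75 (resident), 0.025 (protease), -0.15 (interferon, reversed) and 0.64 (handling stress). Without such genes, macrophage medians of aneurysm over smoke were -0.67 (inflammatory), -0.85 (protease) and 0.17 (MHC class II). Without such genes, the macrophage median of aneurysm over room air was -0.35 (inflammatory). Without such genes, smooth muscle medians of smoke over room air were 0.88 (protease), -0.11 (modulated) and -0.017 (handling stress). Without such genes, smooth muscle medians of aneurysm over smoke were -0.017 (elastic fibre) and -0.56 (handling stress). Without such genes, the fibroblast median of smoke over room air was 0.20 (protease). Without such genes, the fibroblast median of aneurysm over smoke was 0.33 (protease, reversed). Without such genes, the endothelial median of smoke over room air was -0.10 (NRF2). Without such genes, endothelial medians of aneurysm over smoke were -0.81 (aryl hydrocarbon) and -0.030 (activation).

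With no count minimum for list members, macrophage medians of smoke over room air were 0.0018 (inhibitor) and 0.20 (MHC class II).

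With members expected at 5 UMIs or more, the macrophage median of smoke over room air was 0.20 (MHC class II). Among such members, the macrophage median of aneurysm over smoke was 1.63 (resident), and only Tiparp (-0.80) was left of the aryl hydrocarbon list. Among such members, the macrophage median of aneurysm over room air was 1.79 (resident).

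With median-of-ratios scaling, the macrophage median of aneurysm over smoke was -1.06 (lipid). With these factors, the macrophage median of aneurysm over room air was -0.83 (lipid). With these factors, the smooth muscle median of smoke over room air was 0.039 (contractile). With these factors, endothelial medians of smoke over room air were -0.043 (NRF2) and 0.69 (handling stress).

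With TMM scaling, the macrophage median of aneurysm over smoke was -1.07 (lipid). With TMM factors, the macrophage median of aneurysm over room air was -0.83 (lipid). With TMM factors, the smooth muscle median of smoke over room air was 0.060 (contractile). With TMM factors, the endothelial median of smoke over room air was 0.70 (handling stress).

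Other macrophage medians of aneurysm over room air that left their interval follow by list. For proteases they were -0.41 (no filter), -0.41 (median-of-ratios), -0.41 (TMM), -0.57 (without genes below the other nuclei) and -0.41 (members expected at 5 UMIs). For inhibitors they were 0.69 (15 principal components), 1.12 (separate clustering), -0.14 (thinned nuclei) and 1.02 (cluster 0). MHC class II genes gave -0.077 (minimum of 1000 UMIs), 0.38 (no filter), 0.37 (resolution 2), 0.36 (15 principal components), -0.58 (thinned nuclei), -0.084 (all clusters assigned), -0.91 (cluster 0) and -1.23 (cluster 17). NRF2 targets gave -0.68 (cluster 0) and 0.94 (cluster 17), and handling stress genes 0.095 (thinned nuclei) and 0.013 (cluster 17). Proliferation genes gave -1.06 (minimum of 1000 UMIs) and 0.65 (cluster 0, reversed).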

Other observations

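The test of adipocyte-like nuclei and both tests of the macrophage cluster mix were chosen after the results were seen; the tests of depth, striated muscle RNA and doublets were set before. Adipocyte-like nuclei formed a pair of clusters. Cluster 14, led by Car3 and Cidec, held 33, 104 and 650 nuclei of the room air, smoke and aneurysm libraries. Leptin, Lep, was at 40.3, 14.9 and 26.4 CPM there, and Adipoq at 259.8, 166.8 and 160.5 CPM. Cluster 15 held 4, 104 and 597 nuclei. Ucp1, the uncoupling protein of brown fat, is among the genes that define it and was at 495.0 CPM (452.6 to 540.3) in smoke and 782.8 CPM (727.3 to 841.5) in aneurysm. A UMI of Adipoq was found in 38.0% of adipocyte-like nuclei of smoke and 14.6% of aneurysm, and in 9.27% and 8.68% after thinning to 1000 UMIs, which left out 3 and 348 nuclei (median depths 7970 and 1453 UMIs). In endothelial-like nuclei of these libraries (9753.5 and 1819.5 UMIs) the shares were 0.488% and 0.302%, and 0 of 1605 and 0 of 734 after thinning, with 35 and 258 left out.

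Dendritic-like nuclei formed 3 clusters, each nearly empty in the aneurysm library. Cluster 12, led by Il1r2 and also defined by the MHC class II activator Ciita, held 404, 533 and 7 nuclei of room air, smoke and aneurysm. Cluster 20, with the lymph node homing receptor Ccr7 at 432.3 and 491.9 CPM in room air and smoke, held 194, 264 and 2. Cluster 23, with Clec9a, a receptor of cross-presenting dendritic cells, at 342.5 and 398.0 CPM, held 55, 117 and 5. In the unnamed cluster 2 the fibroblast inflammatory list was at 0.89 for aneurysm over smoke, percentile 100, with 6 of 11 members higher and 0 lower, but at -0.18 for aneurysm over room air, percentile 13.4, with 4 higher and 2 lower.

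The lower shares of immune classes in the aneurysm library were weighed against adipose tissue and depth. With adipocyte-like nuclei left out, the macrophage-like share ratio of aneurysm over smoke was 0.397 (0.367 to 0.428). This value follows from shares already seen and is no independent test. It shows only that leaving these nuclei out of the total does not level the shares. With the smoke library thinned to 20% of its UMIs and filtered again, macrophage-like nuclei took 49.5% (48.6 to 50.4), against 13.5% in aneurysm, which argues against depth. For T or NK-like, B-like and dendritic-like nuclei together the thinned share was 9.31% (8.77 to 9.86), against 14.3% unthinned and 0.579% in aneurysm. Loss at that minimum may thus account for part of their difference but not for all of it. Other cells of surrounding fat, the naming of shallow nuclei, the dissection, the bead sort and the aneurysm itself stay open and were not tested.

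Higher resident genes and lower lipid-associated genes in macrophage-like nuclei of the aneurysm library were weighed against the mix of clusters. With clusters weighted as in the smoke library, the resident list was at 0.13 (-0.21 to 0.34) in place of 2.21. Since 3 of its members define these clusters, and its values within clusters had been seen, this test had to remove most of the difference and decides nothing. The lipid-associated list was at -0.38 (-0.46 to -0.32) in place of -0.91 and kept 41.5% of its size. This leaves open whether a finer mix within clusters could account for the rest. Free RNA of macrophages was not tested either. Gpnmb of this list, which endothelial-like nuclei should lack, was at 425.5 and 46.6 CPM in those nuclei of smoke and aneurysm. Why the mix differed was not tested. Smoke with an aneurysm remains an open explanation, and so do macrophages brought in with surrounding fat. Adipocyte-like nuclei took 1.49% of the smoke library and 21.9% of the aneurysm library.

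A UMI of titin, Ttn, was found in 106 of the 339 nuclei (31.3%) of cluster 17 in the aneurysm library. Of these 106 nuclei, 36.8% (27.6 to 46.7) had a UMI of Cdh6, against 11.2% (7.42 to 15.9) of the other 233, and 34.9% against 12.4% had one of Cxcl13. For Cd55 (54.7% against 27.9%) and Col6a5 (25.5% against 4.29%) the intervals were also apart, but for Ms4a8a (35.8% against 24.9%), Saa3 (19.8% against 12.9%) and Lyve1 (17.9% against 12.02%) they overlapped. Nuclei with Ttn were the deeper ones (medians 1454.5 and 1109 UMIs), and these shares are not corrected for that. Free RNA of striated muscle would bring Neb, Trdn, Ryr1 and Tnnt3, of which 4 UMIs were seen and 287.8 expected, a ratio of 0.0139 (0.00379 to 0.0356). Doublets with fibroblasts would bring their markers, which stood at 0.0195 (0.0116 to 0.0308) of their level in fibroblast-like nuclei. Both values argue against these explanations; a macrophage state that is particular to this library may remain, as a hypothesis found and tested on the same data.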
